A study of Mus musculus with 4 samples.

How the data were processed

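RNA from mouse skin was sequenced as QuantSeq 3′ FWD libraries, per the labels' protocols, in 4 samples: 2 treated with DMSO and 2 with NEDD8i. The authors deposited 1 table of raw read counts per gene for 56953 genes, with the exon coordinates and summed exon length of each gene. STAR, featureCounts and DESeq2 are named in the submitters' processing notes, with versions and settings not given in the sources used here, and the column layout is that of featureCounts, per the file headers. The notes name both GRCm38 and GRCm39. Of 52029 genes matched by identifier to GENCODE M21 on GRCm38, 1405 (2.7%) had the same start, so the coordinates printed are those of the deposited table and are taken to be GRCm39, the other build named. Whether the counting used strand, and how it treated reads that fit several genes, is not given in the sources used here. Per the labels' protocols full-thickness skin was taken, while the extraction text speaks of cells.

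Sample groups and replicate numbers were taken from the labels. Every column of the table was matched to 1 sample by its name, and 0 columns of sample values were left unused. Library totals were 5955627 and 5639791 for DMSO replicates 1 and 2, and 8856572 and 8833217 for NEDD8i replicates 1 and 2. Between 52.6% and 61.7% of these counts fell on 3 ribosomal RNA genes, Rn18s-rs5, mt-Rnr1 and mt-Rnr2, so that 2824291, 2287839, 3654442 and 3379890 counts were left for other genes in the same order. All 4 libraries differed from each other beyond sampling noise (chi-square per degree of freedom 27.2 to 76.7), and none was a duplicate. Reads were not collapsed by molecular identifier as far as the sources used here say, so count intervals and floors cover counting error only. A floor of 3 counts corresponds to 0.36 to 0.543 CPM in a library.

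Differential expression was tested in R 4.3.3 with edgeR 4.0.16, on the counts as deposited. TMM factors were 1.18, 0.982, 0.912 and 0.945. Genes were kept by filterByExpr with its defaults (minimum count 10, minimum total 15), which left 11388, and tested with the robust quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05. The model held the group alone. The common dispersion was 0.12, a biological coefficient of variation of 34.6%, and the median standard error of a log2 fold change was 0.42. Log2 CPM used a prior count of 2. Fold changes are NEDD8i relative to DMSO. Where all libraries of the DMSO group had no count, a lower bound was computed from a floor of 3 counts over the group, and with 1 to 3 counts in the group the ratio is given with its 95% counting interval.

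A set of 40 gene lists (24 pathway, 13 cell type and 3 quality lists, 802 distinct genes, 14 of them not analysed here) was fixed before the data were examined, as were the test, the rule for named genes and all alternatives except those said to be added. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the 37 lists that had at least 5 tested members. Camera with an estimated correlation and fry, which tests whether a list's genes move one way without comparing them with other genes, stood beside it, as did fry's test for change in either direction. With an estimated correlation, camera also takes its degrees of freedom from the libraries instead of the genes, which by itself raises p with so few libraries. The 3 lists with fewer members were endothelium (0 tested), smooth muscle and pericytes (3 tested, 0 past the threshold) and mast cells (2 tested, 0 past the threshold). Genes were named by 3 rules. The first took genes past the threshold with both NEDD8i libraries on one side of both DMSO libraries and a mean log2 CPM of at least 2, without predicted gene models, up to 12 in each direction by size of change. Where fewer than 12 passed, the list was filled by smallest p and the gene said to have missed. The second took from each list up to 4 members past the threshold or, where none passed, up to 2 of the most abundant. The third always took Nedd8, Nae1, Uba3, Ube2m and Ube2f.

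Alternatives were DESeq2 1.42.0, limma-voom, RLE factors, library sizes without TMM, no filter and a fixed filter. The fixed filter asked for 10 counts and a CPM above 1 in at least 2 libraries. It kept 11461 genes, more than the 11388 of the default, so it was not stricter in number. Further alternatives were a fit without the robust option, a minimum log2 change of 1, the replicate number as a block, and each library left out in turn. Leaving out the 3 ribosomal RNA genes, and thinning all libraries to one depth without them, were added after seeing the data. The steps were tested on simulated data drawn from these libraries' means and sizes with 200 changed genes. With dispersions on the fitted trend, edgeR recovered 8.51%, 66.7%, 95.9% and 100% of genes changed by 1, 2, 3 and 4 on the log2 scale, over 10845 genes, and 3.76% of its calls were false. With each gene's own dispersion the shares were 4.08%, 55.8%, 83.0% and 97.9% over 10902 genes, and 14.5% of calls were false, above the nominal 5%. In the test of lists, the 1 shifted list was found and 0 of the others were called. Its genes were drawn independently of each other, whereas the estimated correlation in the real hair shaft list was 0.97. The test therefore cannot show whether camera calls hold for lists whose genes are correlated.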

Results

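Gene expression was measured in dorsal skin, full-thickness per the labels, of wild-type C57BL/6J mice after 3 days of topical treatment. One group received NEDD8i at 10 µM, a compound known here only by that label, whose name refers to the ubiquitin-like protein NEDD8. The other group received DMSO, the solvent control. The extraction text speaks of cells and endothelial genes had only 12 to 52 reads per library, so which layers the RNA came from is uncertain, which bears on the fibroblast, matrix and immune values below. Each group had 2 libraries, made with a 3′ tag method that reads the end of each polyadenylated transcript. Total counts were 5955627 and 5639791 in DMSO replicates 1 and 2, and 8856572 and 8833217 in NEDD8i replicates 1 and 2. Ribosomal RNA genes took 52.6%, 59.4%, 58.7% and 61.7% of these counts in the same order. The NEDD8i libraries resembled each other more (Pearson correlation across genes 0.943 on log2 CPM, read counts scaled to library size) than the DMSO libraries did (0.87). DMSO replicate 2 was slightly closer to NEDD8i replicates 1 and 2 (0.886 and 0.887) than to DMSO replicate 1. Genes are not independent replicates in these values. The labels do not say whether replicates came from separate mice, so the edgeR p-values of single genes below measure the spread between these samples, which may be technical. Camera p-values with the preset correlation compare a list's genes with the other genes and treat genes as nearly independent. They therefore do not measure how a list varies between samples. The preset was 0.01, whereas estimated correlations ran from -0.139 for the macrophage list to 0.971 for the hair shaft list.

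The comparison of NEDD8i with DMSO asks which transcripts differ in skin after the topical treatment. Several genes of the cornified envelope that keratinocytes switch on in wounded or irritated epidermis were far higher after NEDD8i. Leading them were the small proline-rich Sprr2 genes, Sprr1a and the late cornified envelope genes Lce3c and Lce3f. The interferon-inducible gene Ifi202b, the alarmin cytokine Il33, the matrix protease Mmp3, the phospholipase Pla2g4e and the serpin Serpinb2 rose with them. The late differentiation genes Lor (loricrin) and Flg2 (filaggrin 2), the mitotic checkpoint kinase Bub1b and the epidermal T cell selection family member Skint7 fell. In all, 89 of 11388 tested genes (0.782%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 76 higher and 13 lower after NEDD8i. The smallest log2 change among them was 1.67 in size. At an unadjusted p under 0.05 there were 1877 genes, 982 higher and 895 lower. The count depended on the libraries kept, as fits that leave 1 library out show below. In such a fit 1 group has 1 library, so its p-values measure no spread within that group. Calls and adjusted p-values from these fits therefore show only how results depend on a library, and are not separate findings.

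Ifi202b (ENSMUSG00000026535.10, chromosome 1, 173790134 to 173810310, minus strand, taken to be GRCm39) went from 4.80 ± 2.95 CPM in DMSO to 599.9 ± 31.7 CPM after NEDD8i (mean ± SD, n = 2 libraries each). Its log2 fold change was 6.98 (SE 0.53, edgeR adjusted p = 0.00247), and its counts were 19 and 38 against 5011 and 4807, while no other counted gene of its cluster exceeded 76 in a NEDD8i library. Sprr2g (ENSMUSG00000046203.13, chromosome 3, 92281222 to 92282536, plus strand) had 1 count in each DMSO library and 327 and 399 after NEDD8i, a ratio of 277 with a 95% counting interval of 76.5 to 2300 (edgeR adjusted p = 0.000853). Sprr1a was the most abundant of the rising genes, at 158.7 ± 1.34 CPM in DMSO and 2503 ± 192 CPM after NEDD8i (log2 fold change 3.98, SE 0.36, edgeR adjusted p = 0.0039). The log2 fold changes of the other genes with the largest rises were 5.40 for Sprr2d, 5.05 for Sprr2h, 4.90 for Sprr2f, 4.82 for Mmp3, 3.96 for Il33, 3.74 for Lce3c, 3.69 for Lce3f, 3.67 for Pla2g4e and 3.50 for Serpinb2. Sprr2 genes are close copies of one another, and reads that fit several of them could be split or lost in counting, so their single values are less certain than the rise of the family. Without NEDD8i replicate 2, Lce3f no longer passed.

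**Figure D1:**
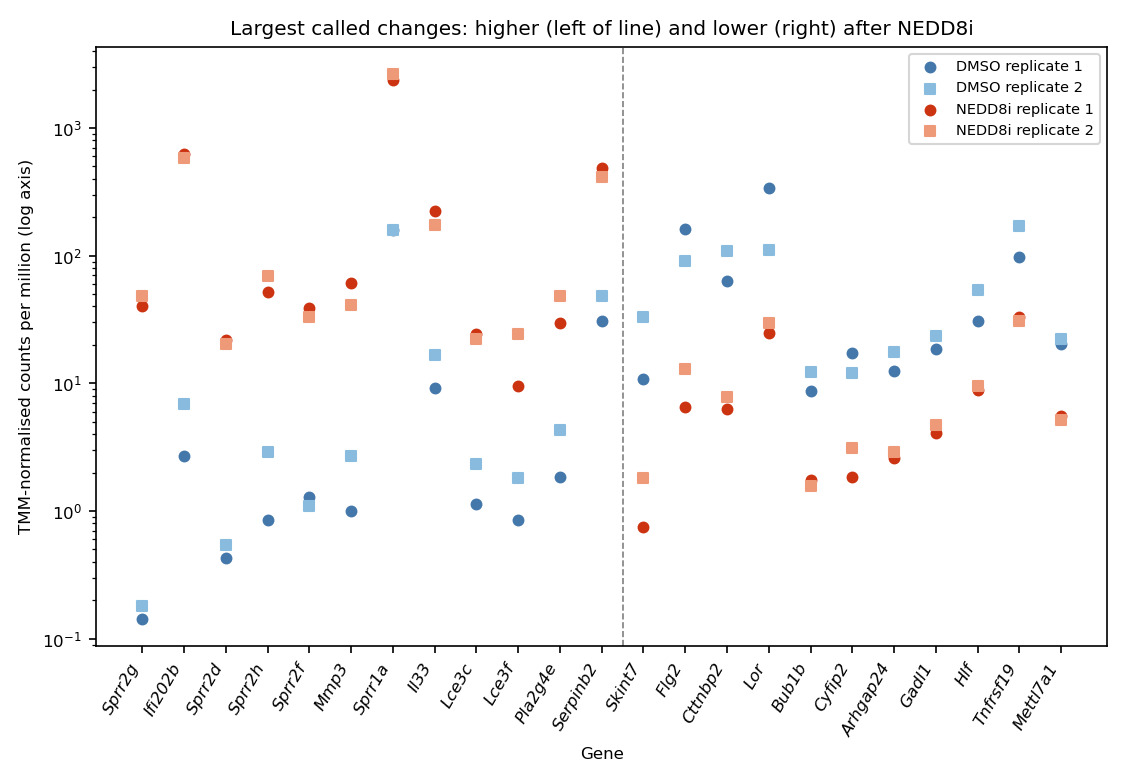
Normalised CPM (log axis) of the genes with the largest called changes, 12 higher and 11 lower after NEDD8i, with 1 point per library. For each gene both NEDD8i libraries lie on one side of both DMSO libraries, as the choice of genes required.

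Among the falling genes, Skint7 went from 22 ± 15.8 to 1.27 ± 0.75 CPM (mean ± SD, n = 2 each), a log2 fold change of -4.08 (SE 0.66, edgeR adjusted p = 0.0347), though Skint genes are close copies that may share reads. Flg2 had a log2 fold change of -3.69 (SE 0.44, edgeR adjusted p = 0.0128), and the cortactin-binding protein gene Cttnbp2 one of -3.61 (SE 0.37, edgeR adjusted p = 0.00574). Lor was at 225.4 ± 162 CPM in DMSO and 27.2 ± 3.51 CPM after NEDD8i, a log2 fold change of -3.05 (SE 0.51, edgeR adjusted p = 0.0377). The remaining genes of this rank were Bub1b at -2.66, Cyfip2 at -2.56, Arhgap24 at -2.45, Gadl1 at -2.25, the circadian-controlled transcription factor Hlf at -2.21, the TNF receptor family member Tnfrsf19 at -2.07 and Mettl7a1 at -1.99. Paqr5 came next at -1.94 and missed the threshold (edgeR adjusted p = 0.0505). The falls were less secure than the rises: without NEDD8i replicate 1 or without NEDD8i replicate 2, 9 of these 11 genes no longer passed, Flg2 and Cttnbp2 being the exceptions.

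The wound and stress keratinocyte list had the smallest camera p of the lists. Of its 25 tested members 13 rose, 0 fell and 12 did not pass (19 higher when adjusted over the list alone), and the median log2 fold change was 3.71, also with Sprr2i, which had no DMSO count, set at its bound. As a group they were higher by camera (adjusted p = 4.5e-39), and adjusted p = 0.289 with an estimated correlation. The passing members were the Sprr and Lce3 genes above except Sprr2g, which is not in the list, S100a8, an antimicrobial calgranulin subunit (log2 fold change 2.28), and, named after their values were seen, the wound keratin Krt6a (3.38), the AP-1 subunit Fosl1 (2.64), Lce3d (4.91), the beta-defensin Defb14 (4.24), Sprr2e and Sprr2i. Sprr2i was at least 25.2-fold higher, taking a floor of 3 counts over the DMSO group. Krt16, also named after its values were seen, had counts of 97 and 633 against 10895 and 15013 and did not pass. Without DMSO replicate 1, 23 members were higher and 1 lower, and without DMSO replicate 2, 23 were higher; 9 were higher without NEDD8i replicate 1 and 10 without NEDD8i replicate 2.

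In the list of normal spinous and cornified layer differentiation, Lor and Flg2 fell. Of 29 tested members 0 rose, 2 fell and 27 did not pass, and 9 had a positive log2 fold change (10 lower and 1 higher when adjusted over the list alone), with a median log2 fold change of -0.68 (camera adjusted p = 0.000135, and adjusted p = 0.673 with an estimated correlation). Flg (-2.34) and Hrnr (-1.76) narrowly missed the threshold over all genes; these, Krt10 and Ivl were named after their values were seen. The early differentiation keratin Krt10 stood at -0.68 and the cornified envelope precursor Ivl at 0.64, neither past it. The basal layer list, with Krt5 at -0.20 and Krt14 at 0.49, had 0 of 15 members past the threshold (1 higher when adjusted over the list alone, median 0.29, camera adjusted p = 0.291). Without DMSO replicate 2 the camera call of basal epidermal keratinocytes passed as higher (adjusted p = 0.00347), with 6 members higher and a median of 0.72, and without DMSO replicate 1 there were 2 higher and 2 lower and a median of -0.07. Without NEDD8i replicate 1 or without NEDD8i replicate 2, 1 spinous and cornified member was lower, against 11 without DMSO replicate 1 and 12 without DMSO replicate 2, where 3 others were higher each time.

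**Figure D2:**
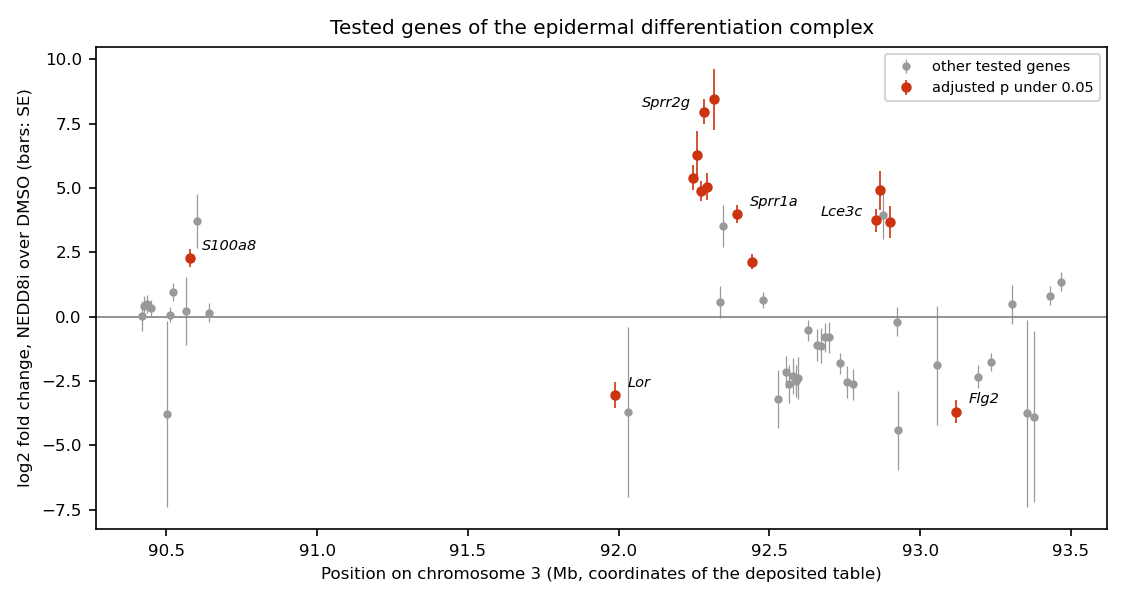
Log2 fold change of NEDD8i over DMSO (points, bars show the SE) for the 53 tested genes between S100a1 and S100a10 on chromosome 3, by position in Mb. The genes past the threshold are 12 higher, which are Sprr and Lce3 genes, S100a8 and 2310046K23Rik, and 2 lower, Lor and Flg2. Sprr2i, the highest point, had no DMSO count, so its fitted value and SE are not a measured fold change. Its bound is at least 25.2-fold.

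Matrix-degrading enzymes were 3 of the 4 genes that rose in the extracellular matrix list, where 4 of 19 tested members rose and 0 fell (9 higher and 1 lower when adjusted over the list alone). Mmp3, Mmp10 and Mmp13 are proteases, and Ccn2 is a matricellular growth factor (log2 fold change 2.38, SE 0.43). Mmp10 had 0 and 1 counts in DMSO and 139 and 119 after NEDD8i, a ratio of 197 with a 95% counting interval of 35.1 to 7820. Mmp13 was at least 19.1-fold higher over the same group floor. The list median was 1.51 (camera adjusted p = 3.01e-10, and adjusted p = 0.336 with an estimated correlation). In the dermal fibroblast list only Dpt (3.29) passed among 10 tested members (6 higher when adjusted over the list alone, median 2.61, camera adjusted p = 0.000212, and adjusted p = 0.673 with an estimated correlation). Of these members 6 had a positive and 4 a negative log2 fold change. The list's share of reads outside ribosomal RNA did not rise. It was 0.0692% and 0.0494% in DMSO replicates 1 and 2, and 0.0487% and 0.0569% in NEDD8i replicates 1 and 2. Col1a1, named after its values were seen, had counts of 15 and 10 in DMSO and 24 and 119 after NEDD8i, so that NEDD8i replicate 2 held most of its reads. Matrix members higher numbered 2 without NEDD8i replicate 1, where Mmp13 was lost, 3 without NEDD8i replicate 2, 11 without DMSO replicate 1, and 11 without DMSO replicate 2, where 1 was lower. The medians were 0.88 for the matrix list and 1.15 for the fibroblast list without NEDD8i replicate 2. Dpt and Ccn2 no longer passed without NEDD8i replicate 1 or without NEDD8i replicate 2. Dpt was also lost with limma-voom, where 0 fibroblast members were called.

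The NF-kB, neutrophil and macrophage lists were higher by camera, on few or no single calls. Il33 and the prostaglandin synthase Ptgs2 (log2 fold change 2.68) rose among 18 tested NF-kB and cytokine genes (4 higher when adjusted over the list alone, median 0.52, camera adjusted p = 0.0021, and adjusted p = 0.673 with an estimated correlation). The neutrophil list had 1 riser among 6 tested, S100a8, which keratinocytes also express and which the wound list holds too (3 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.00488, and adjusted p = 0.673 with an estimated correlation). The neutrophil genes Ly6g, Camp, Ltf and Ngp had 0 counts in all 4 libraries, which allows up to 0.543 CPM in DMSO replicate 2, the shallowest. No macrophage gene of 8 tested passed (2 higher when adjusted over the list alone, median 0.85, camera adjusted p = 0.0171, and adjusted p = 0.673 with an estimated correlation), with C1qa at 1.39. Interferon-stimulated genes gave 0 of 10 past the threshold (0 when adjusted over the list alone), with a median of 0.03, a mean of -0.02 and a downward camera direction (adjusted p = 0.952). Without NEDD8i replicate 1 the neutrophil and macrophage lists lost their camera calls and Ptgs2 and S100a8 no longer passed. The camera call of monocytes and macrophages was also lost with the fixed filter (adjusted p = 0.0573) and after thinning (adjusted p = 0.0916). NF-kB members higher were 4 without DMSO replicate 1, 5 without DMSO replicate 2, 1 without NEDD8i replicate 1 and 3 without NEDD8i replicate 2, and neutrophil members 3, 4, 0 and 1 in that order, with 1 lower without DMSO replicate 2. Macrophage members higher were 2, 3, 0 and 1, with 1 lower without DMSO replicate 2.

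The G2/M and G1/S lists were lower by camera, with few single calls. In the G2/M list Bub1b fell among 25 tested members (8 lower when adjusted over the list alone), the median was -1.01, and 23 members had a negative log2 fold change (camera adjusted p = 3.93e-08, and adjusted p = 0.673 with an estimated correlation). The G1/S and replication list had 0 of 24 past the threshold (1 lower when adjusted over the list alone), with Mcm3 at -1.08 and a median of -0.75 (camera adjusted p = 0.00167, and adjusted p = 0.749 with an estimated correlation). Cholesterol synthesis genes had 0 of 21 past it (1 higher and 2 lower when adjusted over the list alone), with Hmgcs1 at -1.16 and a median of -0.55 (camera adjusted p = 0.00544, and adjusted p = 0.722 with an estimated correlation). Barrier lipid genes had 0 of 17 (0 when adjusted over the list alone) and a median of 0.49 (camera adjusted p = 0.0173, and adjusted p = 0.673 with an estimated correlation), and Notch, Wnt and Hedgehog genes 0 of 12 (1 lower when adjusted over the list alone) and a median of -0.65 (camera adjusted p = 0.0351, and adjusted p = 0.749 with an estimated correlation). Without NEDD8i replicate 1 or without NEDD8i replicate 2, Bub1b no longer passed. It was also lost with limma-voom and with library sizes without TMM. G2/M members lower were 8 without DMSO replicate 1 and 10 without DMSO replicate 2. The camera calls of the G1/S, barrier lipid and Notch lists were lost without DMSO replicate 1, those of the Notch and cholesterol lists without NEDD8i replicate 1 and that of the barrier lipid list without NEDD8i replicate 2. The camera call of Notch, Wnt and Hedgehog targets was also lost with library sizes without TMM (adjusted p = 0.0628). Without DMSO replicate 2 members lower were 5 in the G1/S list, 5 in the cholesterol list and 6 in the Notch list, and 3 barrier lipid genes were higher and 1 lower. The Notch list took 0.123% of reads outside ribosomal RNA in DMSO replicate 1, the library with most hair RNA, against 0.0654%, 0.0581% and 0.0786% in the others. Its median went to -0.01 without that library, and the G1/S median to -0.33. In that fit, without DMSO replicate 1, the G1/S list had 1 lower, the cholesterol list 1 higher and 3 lower, and the Notch and barrier lipid lists 1 higher each.

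**Figure D3:**
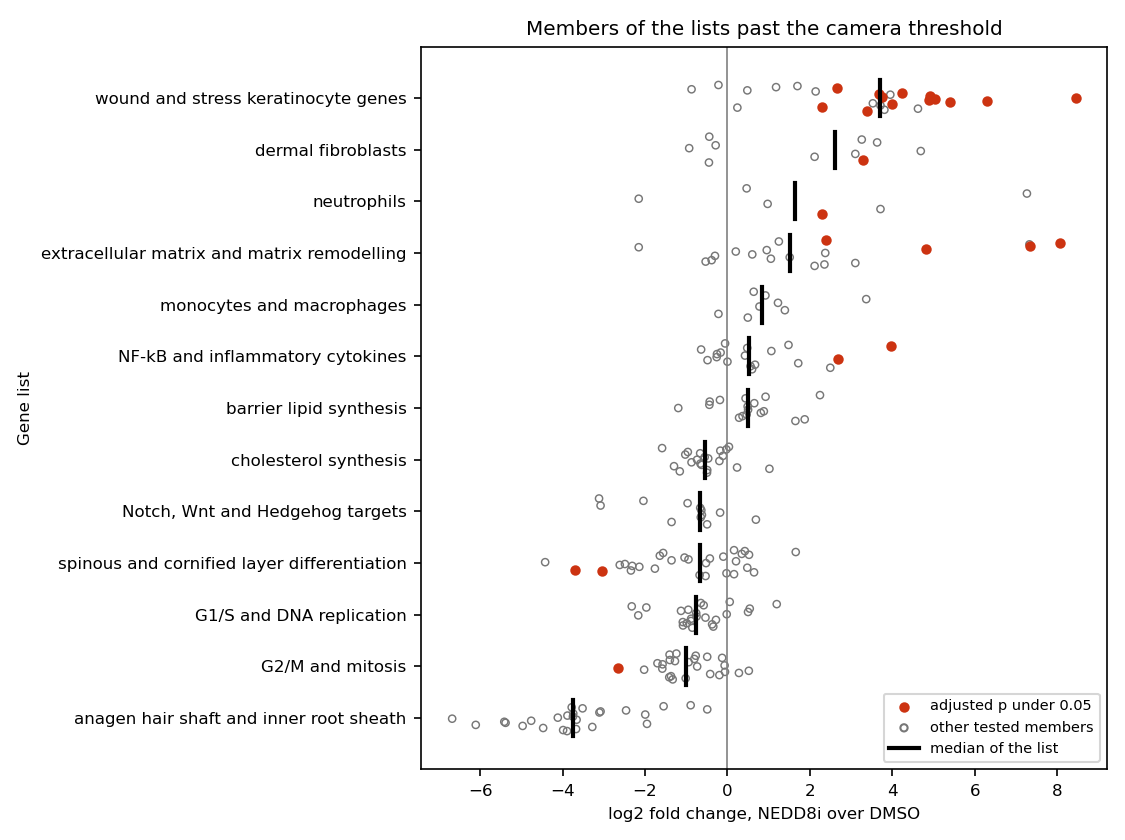
Log2 fold change of NEDD8i over DMSO for each tested member (points) of the 13 lists past the camera threshold, with the list median as a bar. Filled points passed an adjusted p of 0.05 over all genes tested, 13 of them in the wound and stress keratinocyte list. Members without a DMSO count, such as Sprr2i and Mmp13, are drawn at their fitted values, which are not measured fold changes.

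Hair shaft and inner root sheath genes varied by library and not by group, by far highest in DMSO replicate 1 and next in NEDD8i replicate 2. They took 2.02% of the reads outside ribosomal RNA in DMSO replicate 1 (exact 95% binomial interval 2 to 2.04), against 0.0196% in DMSO replicate 2, 0.0154% in NEDD8i replicate 1 and 0.137% in NEDD8i replicate 2. Trichohyalin, Tchh, had 25617, 83, 115 and 2158 counts in that order. All 26 tested members had a negative log2 fold change (median -3.74), 0 passed, 0 when adjusted over the list alone, and the list was lower by camera (adjusted p = 0.0149, and adjusted p = 0.905 with an estimated correlation, here 0.97). Without DMSO replicate 1 the camera call of anagen hair shaft and inner root sheath genes turned upward (adjusted p = 2.86e-06), with 14 members higher and a median of 3.89, which rested on NEDD8i replicate 2. Without DMSO replicate 2, 29 members were lower, and without NEDD8i replicate 1 the camera call was lost (adjusted p = 0.277), as it was with library sizes without TMM (adjusted p = 0.165). Melanocyte list reads were also most numerous in DMSO replicate 1, at 2634, of which Dct held 1817, against 224, 333 and 354 Dct counts in the others. Mitf was nearly even, with 94, 82, 107 and 124 counts in library order. The melanocyte list had 0 of 6 members past the threshold (camera adjusted p = 0.315).

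**Figure D4:**
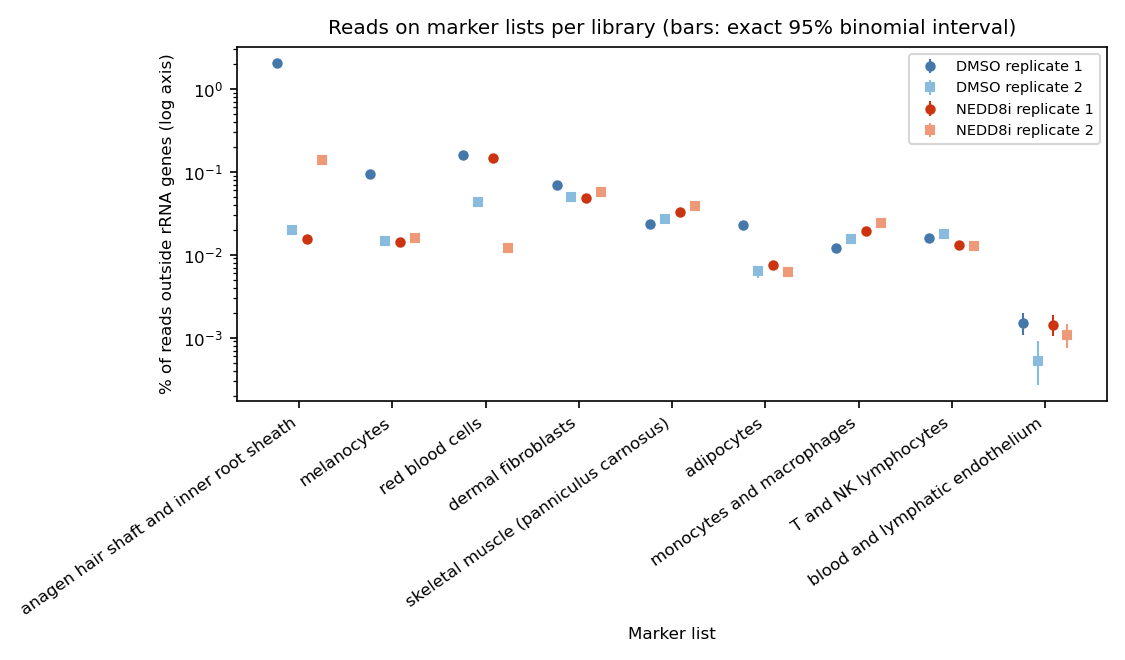
Percent of reads outside ribosomal RNA genes (log axis) on 9 marker lists in each library, with exact 95% binomial intervals that cover counting error alone. Hair shaft genes reach 2.02% in DMSO replicate 1 and endothelial genes reach at most 0.00149%.

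None of Nedd8, Nae1, Uba3, Ube2m and Ube2f, which encode NEDD8 and its activating and conjugating enzymes, passed the edgeR threshold. Nedd8 was at 117.8 ± 19.3 CPM in DMSO and 136.1 ± 21.9 CPM after NEDD8i (log2 fold change 0.21, SE 0.30, edgeR adjusted p = 0.791). The subunits of its activating enzyme, Nae1 and Uba3, stood at 0.73 (SE 0.28) and 0.42 (SE 0.30), and its conjugating enzymes Ube2m and Ube2f at 0.35 (SE 0.40) and 0.82 (SE 0.43). The neddylation and cullin ligase list had 0 of 21 members past the threshold (0 when adjusted over the list alone, median 0.21, camera adjusted p = 0.338), and fry's test for change in either direction gave an adjusted p of 0.0202. NRF2 targets had 0 of 20 past the threshold (4 higher when adjusted over the list alone, median 0.09, camera adjusted p = 0.448) and p53 targets 0 of 20 (1 higher when adjusted over the list alone, median 0.25, camera adjusted p = 0.315). Without DMSO replicate 1, 5 NRF2 targets were higher and 1 lower, without DMSO replicate 2 there were 3 higher, and without NEDD8i replicate 2 there was 1. In both fits without a DMSO library 1 p53 target and 1 neddylation gene were higher, and without DMSO replicate 2 a p53 target was lower. DESeq2 called 3 NRF2 targets higher and the test without a filter 4. Of 19 hypoxia targets the stress-responsive gene Ndrg1 (log2 fold change 2.33) and the vasodilator peptide gene Adm (3.19) rose (2 when adjusted over the list alone, camera adjusted p = 0.166). Without NEDD8i replicate 2 neither Ndrg1 nor Adm passed, and Ndrg1 was also lost without NEDD8i replicate 1. The median of the NRF2 list turned to -0.13 with library sizes without TMM, -0.20 without DMSO replicate 1, -0.15 without DMSO replicate 2 and -0.07 without NEDD8i replicate 1.

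Of the 37 lists tested, 24 were not called, with camera adjusted p from 0.0746 to 0.952 and medians from -1.60 to 0.74. Among these were proteasome subunits (0 of 31 members past the threshold), ubiquitin and SUMO conjugation genes (0 of 16), the unfolded protein response (0 of 18), heat shock genes (0 of 13), chemokines (0 of 10, with 3 higher and 1 lower when adjusted over the list alone) and T and NK lymphocyte markers (0 of 10). The camera call of proteasome subunits passed as higher without DMSO replicate 1 (adjusted p = 0.0163, median 0.38, 29 of 31 positive), and so did the camera call of heat shock response genes (adjusted p = 0.0453, median 0.52, 12 of 13 positive). The Langerhans cell, ribosomal protein and immediate early lists were then called too, and the melanocyte and red cell lists were called without DMSO replicate 2 and without NEDD8i replicate 1, the melanocyte list also with no filter. Without DMSO replicate 1 the unfolded protein response list had 4 members higher and 1 lower, ubiquitin and SUMO genes 2 and 1 and chemokines 2 and 0; without DMSO replicate 2 these were 2 and 1, 1 and 0, and 3 and 1. The median and the test differed in sign for the antigen presentation list (median 0.19, mean -0.06, lower by camera), the sebaceous list (-0.05, 0.12, higher) and the Schwann cell list (0.23, -0.38, lower), and the mean alone did for adipocytes (0.20, -0.10, higher). With a correlation estimated from the data 0 lists were called (lowest adjusted p 0.289, 2 lists at an unadjusted p under 0.05), and fry called 0 (lowest adjusted p 0.101, 8 lists at an unadjusted p under 0.05). Correlation is not the only change there, since camera then also takes its degrees of freedom from the libraries. In the extracellular matrix list the estimated correlation was -0.025, below the preset 0.01, yet the camera p went from 1.63e-11 to 0.0181. Fry's test for change in either direction called 4 lists: the neddylation and wound lists (adjusted p = 0.0202 each) and the chemokine and extracellular matrix lists (adjusted p = 0.0313 each).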

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

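Leaving out ribosomal RNA genes and thinning were the tests chosen only after the data were seen. The 89 changed genes kept their direction in every alternative, but their number did not hold. Against 89 (76 higher, 13 lower), DESeq2 called 415 (236 and 179), limma-voom 27 (25 and 2), library sizes without TMM 47 (38 and 9), no filter 703 (385 and 318) and the fit without the robust option 48 (45 and 3); the cause was not tested. RLE factors (81) and the fixed filter (84) stayed within 1.5 times, as did leaving out ribosomal RNA genes (77) and thinning (87). A minimum log2 change of 1 could remove no gene, since the smallest called change was 1.67. Without TMM the median log2 fold change of all genes moved to -0.22, and the share of calls that were higher went from 85.4% to 80.9%. Leaving out 1 library gave 44 to 1358 changed genes, 41 to 692 higher and 3 to 712 lower. The lone library is then assumed to vary like the other group, and the DMSO libraries were the farther apart, so counts rose without a DMSO library (1285 and 1358) and fell without a NEDD8i library (44 and 46). The replicate numbers are shared between groups without a stated meaning (correlation of same-number deviations -0.13), and as a replicate block they gave 285 genes (179 higher, 106 lower), 2 NRF2 targets among those higher, and the camera call of anagen hair shaft and inner root sheath was lost (adjusted p = 0.224). For the 31 named genes past the threshold, 350 of 434 checks gave the same call and 84 a weaker one. Members called moved both ways. Wound genes higher went from 13 to 8 without TMM, 8 without the robust option, 5 with limma-voom and 17 with DESeq2. Matrix genes higher went from 4 to 2, 2, 1 and 7 in that order. Spinous and cornified genes lower went from 2 to 10 with DESeq2 or no filter, and G2/M genes lower from 1 to 4 with DESeq2. Of the 13 lists called, an estimated correlation left 0 (2 lists at an unadjusted p under 0.05) and fry 0 (8 lists), while in the other alternatives 8 to 13 of them stayed called, the hair shaft list in the opposite direction without DMSO replicate 1, among 10 to 16 lists called in all. Leaving out 1 library put the log2 fold change of Tchh between -7.02 and 3.18, the log2 fold change of Fabp4 between -4.06 and 4.39 and the log2 fold change of Hbb-bs between -3.08 and 1.48. Each highest value came without DMSO replicate 1, where the DMSO group had 1 library and no spread of its own. For Hbb-bs the NEDD8i libraries, at 334.9 and 22.47 CPM, then lay on both sides of DMSO replicate 2, at 63.21 CPM. The adjusted p behind the camera call of anagen hair shaft and inner root sheath ranged from 1.19e-112 to 0.277, and its direction reversed without DMSO replicate 1 (2.86e-06), the library with most of the hair RNA. Weak changes are mostly missed at this depth, spread and number of libraries: simulated changes of 1 on the log2 scale were recovered in 8.51% of genes with dispersions on the trend and in 4.08% with each gene's own.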

Other observations

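All tests in this part were chosen only after the results were seen, and genes not named above were chosen after their values were seen. Growth factor genes of the EGF family were among the called genes outside the fixed lists: Epgn (log2 fold change 3.40, SE 0.33) and Tgfa (2.67, SE 0.36) rose, as did Nrg1 (4.81, SE 0.69, with counts of 1 and 4 against 118 and 76). The other tested ligands went both ways, with Areg at 1.70, Hbegf at 1.18, Ereg at -0.22, Nrg2 at -1.70 and Btc at -2.40, none past the threshold. A shared rise of the family was not seen beyond the 3 called genes: the whole family gave a camera p of 2.52e-05 (0.0612 with an estimated correlation), but the other 5 gave 0.791, which decides nothing with members going both ways. Without TMM 2 of the family were called. The cytokine gene Il24 (0 and 2 counts against 91 and 122, ratio 81.4, 95% counting interval 22.3 to 677) and the protease inhibitor gene Slpi (at least 43.3-fold higher over a group floor of 3 counts) rose too.

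Skint genes encode butyrophilin-like proteins of the epidermis and thymus. Besides Skint7, 9 of the other 10 tested members had a negative log2 fold change, with Skint9 at -1.91 and Skint6 at -0.87. Skint8, with 10 and 9 counts against 0 and 0, was at least 8.29-fold lower over the same floor and did not pass, and Skint11 was at 0.07, a sign that turned without TMM. A candidate hypothesis is that the family is lower as a group: the camera p was 4.14e-10 with Skint7 and 4.08e-08 without it, and 0.0365 without it with an estimated correlation. The members are close copies, so shared reads may link their values. In the epidermal differentiation complex (S100a1 to S100a10, chromosome 3, 90418341 to 93471950), 14 of 53 tested genes were called, against 75 of 11335 elsewhere (odds ratio 53.7, 95% interval 25.8 to 107, 2-sided Fisher exact p = 2.05e-18). Neighbouring genes are not independent, and this region was looked at because its genes led the changes. Within it the 6 tested Sprr2 genes, Sprr1a, Lce3c, Lce3d and Lce3f were higher and Lor and Flg2 lower. Sprr1b (3.53) and Lce3e (3.95) did not pass, and all 12 tested Lce1 genes had negative log2 fold changes and 0 passed.

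The rise of the wound and stress keratinocyte list was set against 3 technical or compositional explanations. Hair RNA in DMSO replicate 1 cannot account for it: against DMSO replicate 2, the lower of the NEDD8i libraries was still higher by a median of 2.73 on the log2 scale over 25 members (lower quartile 1.86). Depth and ribosomal RNA share also fail, since 11 of the 13 called members were still called after both were equalised. A larger share of differentiated keratinocytes would raise spinous and cornified genes alike, and their median was -0.68 (upper quartile 0.16, against a lower quartile of 2.14 in the wound list). A response to the compound, and any difference in handling, scratching or mouse that follows the groups, stay open and untested.

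Ifi202b lies in the Ifi200 cluster on chromosome 1, where Ifi205, Gm7897 and Gm18445 were called too and all 10 tested genes of the cluster had positive log2 fold changes. The tested interferon-stimulated genes elsewhere had a median of 0.03. Only 10 of the 27 genes of that list were tested, so most could not be assessed. The 26 counted held 269 and 291 reads in DMSO replicates 1 and 2, and 458 and 298 in NEDD8i replicates 1 and 2. No other counted member of the cluster held reads near those of Ifi202b, since the highest other count in a NEDD8i library was 76, against at least 4807 for Ifi202b. Reads of another member that were assigned to Ifi202b would not show in these counts. This stays open, as the treatment of reads that fit several genes is not given. Whether the weaker members reflect their own transcripts cannot be told: 5 of them held 4.79% of their joint reads with Ifi202b after NEDD8i (95% interval 4.39 to 5.22) and 14.9% in DMSO (7.40 to 25.7, on 10 reads), so spill from Ifi202b on top of a few own reads may suffice. A strain difference at this locus, which is known to vary between inbred strains, remains possible although all samples are labelled C57BL/6J: 0 of 26 other tested genes within 2 Mb were called, which a difference limited to the cluster would also give. A response to the compound, and handling or mouse differences that follow the groups, also stay open and untested.

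The fall of the hair shaft list follows 1 library. Without DMSO replicate 1 its median turned to 3.89, with 23 of 26 members positive, a turn that rests on NEDD8i replicate 2. In the full data 23 of 26 members were lower in DMSO replicate 2 than in NEDD8i replicate 2, but only 10 were lower than in NEDD8i replicate 1, so an effect of NEDD8i on top of patchy hair growth stays open. A patch of growing follicles in the specimen of DMSO replicate 1 is a candidate source. Its melanocyte list reads, mostly on Dct, were high too, while Mitf was nearly even across libraries. Nothing in the labels gives hair cycle stage.

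With 4 libraries there are 3 splits into 2 and 2, too few for a share under 0.05: the real split gave 89 genes, 1 of the 3 reached that number, and the highest of the others gave 0. The other splits mix DMSO and NEDD8i libraries in each group, so any difference between the real groups widens the spread there. A low number was therefore likely in them, and 89 against 0 decides nothing. Reads on lists of deeper skin differed widely in number, given here for DMSO replicates 1 and 2 and NEDD8i replicates 1 and 2. Endothelial genes had 42, 12, 52 and 36, dermal fibroblast genes 1954, 1131, 1780 and 1924, and skeletal muscle genes 664, 624, 1183 and 1305. Of the muscle reads Tpm2 held 314, 311, 748 and 697, and Myh4 held 71, 46, 40 and 97. Of the fibroblast reads the only called member, Dpt, held 7, 3, 56 and 73. Such totals can rest on few genes and do not measure the amount of deeper skin. Of clock-related genes Hlf fell, Dbp was at -1.97 and Tef at -0.76, Nr1d1 at 0.92 and Arntl at 0.55, and the other 13 genes of that group gave a camera p of 0.723.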
